A study of Homo sapiens with 14 samples.

How the data were processed

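RNA from the 14 samples described under the labels was hybridised to one-colour Affymetrix 3′ expression arrays, and 1 table of processed values covers all of them. Per the labels' protocols, total RNA was extracted with a column kit and a DNase step, amplified and labelled with biotin by the maker's procedure for small samples. The deposited table holds, per the values themselves, linear signal intensity per probe set, not logged, between 0.58 and 14223.48 with 2 decimals. The software that summarised the probe sets and any scaling between arrays are not given in the sources used here. Means of the arrays trimmed by 2% on each side ran from 129.44 to 164, so no common trimmed mean had been set exactly. The scale is thus known, and whether arrays were scaled to each other stays unknown. Median intensities of replicates 1 and 2 were 46.3 and 47.3 in untreated cells, 49.8 and 50.7, 52.99 and 49.5, and 48.1 and 48.9 after scrambled siRNA at 24, 48 and 72 h, and 46.75 and 50.0, 50.4 and 48.4, and 49.2 and 48.5 after PAX3-FOXO1 siRNA. Between 1.79% and 2.45% of the values were identical between the replicates of a group, so no array was a copy of its replicate. Arrays of different groups were not compared in this way.

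Groups and times came from the sample labels. The array holds 22283 probe sets, 68 of them controls. The probe table assigned 19071 to 1 gene, 1043 to several and 2169 to none. Identifiers of 19059 of the single-gene probe sets matched the current human gene table, and 0 symbols had to be updated. Values under 16 were set to 16 and log2 was taken, as had been foreseen for linear values. For each of 11963 genes the probe set with the highest mean over all arrays was kept. The 1127 genes at the floor on every array were left out, which left 10836. Probe sets with several genes or none were tested apart and are not named.

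Tests used limma 3.58.1 in R 4.3.3. A mean was fitted for each of the 7 groups over all 14 arrays, which gave 7 residual degrees of freedom and, with a spread moderated along an intensity trend, a median of 3.09 prior degrees of freedom. Comparisons were PAX3-FOXO1 siRNA against scrambled siRNA at each time, their mean over the times, the difference of the effect between 72 h and 24 h, scrambled siRNA against untreated cells over the times, and scrambled siRNA at 72 h against 24 h. Tests were two-sided, with Benjamini-Hochberg adjustment over the genes and a threshold of 0.05. Counts at an unadjusted p under 0.05 are to be read against a share of 0.05 of the 10836 genes, expected with no effect. Errors beside log2 differences are limma's standard errors, n is 2 arrays per group, and mean intensities are geometric. Each of 24 gene lists was tested in each comparison with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, beside camera with an estimated correlation and fry. Of 704 listed genes 632 are on the array. The lists were reported fusion targets, contractile muscle genes, myogenic regulators, G1/S and replication, G2/M and mitosis, cyclins and cyclin kinase inhibitors, apoptosis, p53 targets, interferon response, FOXO targets, FGF receptor and MAP kinase feedback, IGF and insulin signalling, extracellular matrix, cell adhesion, neuronal genes, cholesterol synthesis, endoplasmic reticulum stress and amino acid response, hypoxia and glycolysis, ribosomal proteins, oxidative phosphorylation, and markers of epithelial, blood, endothelial and fibroblast cells. For the 30 called list results the median, the mean and the test had 1 sign. Among lists without a call they could differ, as for FOXO targets at 24 h (median 0.09, mean -0.05). The comparisons, tests, lists, the rule for named genes and most alternatives were set before the data were examined.

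Genes were named by rule. In each comparison these were the 8 genes with the largest positive and the 8 with the largest negative log2 difference among those past the threshold whose groups did not overlap at any time compared (5 each way for the difference between times, without the overlap condition), PAX3 and FOXO1, and up to 3 members of each list at either end. A gene at the floor on all arrays of 1 side has a fold only as a lower bound.

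Whether replicate numbers pair the samples was checked on the arrays. The deviations of same-numbered arrays from their group means correlated at 0.07 to 0.40 over the 21 pairs of groups, over 0.1 in 19 of them, and at 0.22 to 0.35 for groups compared directly. The labels do not say what a number stands for. All 21 correlations were above 0, so same-numbered arrays may share a batch. As 2 of them did not exceed 0.1, the numbers were not taken as pairing the samples. The fit with the replicate number as a block is given only as a limit on the results. The counts of that fit had been seen in the same output as this check, and an earlier reading that looked only at groups compared directly, which would have taken the numbers as pairing, was set aside. The difference between the 3′ and 5′ probe sets of GAPDH was higher in replicate 2 than in replicate 1 in 6 of 7 groups (means 2.51 and 2.09 on the log2 scale). That of ACTB went either way. In replicates 1 and 2 it was 2.80 and 2.64 in untreated cells, and 3.10 and 3.20 after scrambled siRNA at 72 h.

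The procedure was tested on simulated arrays with the real means and spreads of 10836 genes, 100 of which were changed by 1 and 100 by 2 on the log2 scale, all taken from genes well above the floor. For the comparison at 24 h it recovered 48% and 91% of these, with 6 false calls, at 48 h 47% and 91%, with 13 false calls, and at 72 h 45% and 91%, with 7 false calls. In a simulated shift of the contractile list, camera ranked that list 1 and called 0 of the 22 unshifted lists that share no gene with it. The simulated genes were drawn independently of each other, so this could not test calls of lists whose genes vary together. In the real arrays the estimated correlation was 0.315 for G1/S and replication and 0.326 for G2/M and mitosis. Alternatives were quantile normalization, centring on medians, genes in the upper 60% by mean only, every probe set on its own, the mean of a gene's probe sets, no intensity trend, the replicate block, only the arrays compared, at least a 2-fold change, and leaving out each replicate. Floors of 32 and none, and leaving out PAX3-FOXO1 siRNA 24 h replicate 1 everywhere, were added after seeing the data. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.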

Results

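Rh4 is an established human cell line of alveolar rhabdomyosarcoma, a soft tissue cancer whose cells carry features of developing muscle. These tumours often carry PAX3-FOXO1, a fusion gene that joins the DNA-binding part of the transcription factor PAX3 to the activating part of FOXO1. Gene expression was measured on 14 one-colour Affymetrix arrays in 7 groups of 2. The groups were untreated cells, cells given a scrambled control siRNA for 24, 48 or 72 h, and cells given an siRNA against PAX3-FOXO1 for the same times, with each siRNA at 20 nM. The median intensity of an array lay between 46.3 and 52.99, and between 24.8% and 27.9% of the probe sets of an array lay under an intensity of 16, which was taken as the floor. The number of arrays, 2 per group, limits the precision of every value below. The labels do not say that the replicates of a group are separate cultures, so the p-values measure only the spread between these samples.

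The targeted transcript was read first, through each probe set of its 2 partner genes. The 3 probe sets of PAX3 were at or near the floor on all arrays. Their highest intensities were 10.2, 23.3 and 26.0, and 0, 4 and 5 of the 14 arrays lay above 16. FOXO1 was well measured by each of its 2 probe sets. The brighter probe set had mean intensities of 576, 501 and 575 after scrambled siRNA at 24, 48 and 72 h and of 460, 510 and 501 after PAX3-FOXO1 siRNA, a log2 difference over the 3 times of -0.17 ± 0.15 (SE, adjusted p = 0.681). The dimmer probe set had 312, 362 and 411 after scrambled siRNA and 235, 344 and 235 after PAX3-FOXO1 siRNA, a difference of -0.43 ± 0.18 (SE, adjusted p = 0.291), with -0.80 at 72 h (adjusted p = 0.435). It passed only in the limma fit with the replicate number as a block (adjusted p = 0.0143 over the times and 0.0248 at 72 h), so its call depends on whether the numbers pair the samples. Untreated cells had 634 and 299 on these probe sets. Where the probe sets lie on the transcripts was not analysed here. FOXO1 probe sets may also read the transcript of the unfused FOXO1 gene, so neither a size of the knockdown nor a check of the labels can be drawn from them.

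The comparison at 24 h asked which genes had changed early after siRNA against the fusion. Among 10836 genes tested 33 were lower and 6 higher, against 22 lower and 16 higher without PAX3-FOXO1 siRNA 24 h replicate 1, with 19 of the 39 genes shared. KHDRBS3, an RNA-binding regulator of splicing, fell most, from an intensity of 449 to 60.2 (log2 difference -2.90 ± 0.22 SE, adjusted p = 0.000624). DOCK10, an exchange factor for small GTPases, was at least 5.92-fold lower (adjusted p = 0.00536), with replicate 1 of PAX3-FOXO1 siRNA at the floor. The growth factor receptor FGFR2 was 4.78-fold lower (adjusted p = 0.00829). The AMPA receptor subunit GRIA2 (-2.17), the secreted protein FAM3C (-2.06), the mesenchymal transcription factor FOXF1 (-1.95), the retinaldehyde dehydrogenase ALDH1A3 (-1.87) and the ligand BMP5 (-1.78) also fell, with adjusted p between 0.000624 and 0.0279. PALMD, a cytosolic protein related to the paralemmins, rose 6.63-fold (2.73 ± 0.28 SE, adjusted p = 0.00536). MYL1, an alkali light chain of fast skeletal myosin, rose 3.46-fold, from 98.3 to 340 (adjusted p = 0.0351). The MAP kinase phosphatase DUSP4 (1.34), the tyrosine kinase BTK (1.22) and the inositol phosphate kinase ITPK1 (1.16) rose too. The apolipoprotein APOC1, at the floor in the controls, was at least 1.46-fold higher, with an intensity of 23.3. It lay at the floor in every other group, so the floor hid most of the spread behind its call.

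Of 33 measured genes that earlier work named as targets of the fusion, 0 rose, 7 fell and 26 did not pass at 24 h (17 lower and 1 higher adjusted over the list alone). Besides FOXF1 and BMP5, they included NELL1, a secreted protein of bone formation (-1.71, adjusted p = 0.0279), and the stress response gene GADD45A (-1.60, adjusted p = 0.0279). The list as a whole was lower than other genes (median -0.54, camera adjusted p = 8.04e-14, and adjusted p = 0.0525 with an estimated correlation). It was put together partly from fusion knockdowns, possibly on these arrays, so its direction is not independent evidence. Of 48 contractile muscle genes, MYL1 alone rose and 0 fell (2 and 0 adjusted over the list alone). The list median was 0.16 (camera adjusted p = 0.000286, and adjusted p = 0.103 with an estimated correlation). TNNC2, the fast troponin C, did not pass (2.82-fold, adjusted p = 0.288). None of 38 genes of G1/S and DNA replication passed by limma. The list median was -0.15 (camera adjusted p = 0.0332), with 0 higher and 4 lower adjusted over the list alone and adjusted p = 0.695 with an estimated correlation. The fibrillar collagen COL3A1 fell by 0.71 (adjusted p = 0.0389), the one fibroblast marker that passed. Replicate 1 of PAX3-FOXO1 siRNA at 24 h had the highest difference of all arrays between the 3′ and 5′ probe sets of ACTB (3.45 on the log2 scale), and it shared the lowest median correlation with the other arrays, 0.965, with replicate 2 of PAX3-FOXO1 siRNA at 72 h. The count of 39 genes was 2 without scrambled siRNA 24 h replicate 1, 3 without scrambled siRNA 24 h replicate 2 and 285 without PAX3-FOXO1 siRNA 24 h replicate 2. It was 67 after quantile normalization, 97 in the upper 60% of genes by mean, and 0 with the 4 arrays of this time alone (limma, 962 at an unadjusted p under 0.05).

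At 48 h the comparison asked the same of a later time, and the largest rises included genes of the contractile apparatus. TNNC2 rose 30.9-fold, from 59.2 to 1830 (log2 difference 4.95 ± 0.49 SE, adjusted p = 0.00108). The myosin-binding protein MYBPH rose 16.5-fold (adjusted p = 0.000279), the fast troponin I TNNI2 11.3-fold (adjusted p = 0.00736), and the myosin light chains MYL1 and MYL11 9.45-fold and 9.25-fold (adjusted p = 0.000714 and 0.00027). PALMD (3.27), the regulator of G-protein signalling RGS2 (3.15) and the leucine-rich membrane protein LRTM1 (3.04) rose as well. In all, 60 genes were higher and 34 lower. Among those lower were the neuroendocrine transcription factor INSM1 (-2.42 ± 0.40 SE, adjusted p = 0.0245), the secreted glycoprotein RELN (-2.01), FGFR2 (-1.80), the TGF-beta co-receptor TGFBR3 (-1.68), the pipecolate oxidase PIPOX (-1.65), the cannabinoid receptor CNR1 (-1.60), NELL1 (-1.55) and ALDH1A3 (-1.52), with adjusted p between 0.0117 and 0.0454.

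Of the 48 contractile genes, 14 rose, 0 fell and 34 did not pass at 48 h (25 and 0 adjusted over the list alone). Their median was 0.56 (camera adjusted p = 1.68e-33), and this call held with an estimated correlation (adjusted p = 0.000358). Of the 20 measured regulators of muscle development none passed by limma, with 2 higher adjusted over the list alone. MEF2C, a partner of the myogenic factors, had 1.26 (adjusted p = 0.0683). The median was 0.34 (camera adjusted p = 0.00211, and adjusted p = 0.344 with an estimated correlation). Of the reported fusion targets 8 fell, CNR1, PIPOX and the P-cadherin CDH3 among them, and 2 rose (16 and 2 adjusted over the list alone). The pair that rose was TNNC2, which is also on the contractile list, and the Ras-association protein RASSF4 (1.61, adjusted p = 0.0477). The target list's median was -0.55 (camera adjusted p = 3.04e-10, and adjusted p = 0.0634 with an estimated correlation), again not independent evidence. TYMS, the thymidylate synthase, fell by 0.71 (adjusted p = 0.0326), 1 of 38 genes of G1/S and replication. That list's median was -0.31 (camera adjusted p = 4.15e-08, 0 higher and 2 lower adjusted over the list alone, adjusted p = 0.382 with an estimated correlation). The 42 genes of G2/M and mitosis had a median of -0.30 with 0 passing by limma (camera adjusted p = 3.24e-06, and adjusted p = 0.479 with an estimated correlation). The receptor ERBB3 (1.28), DUSP4 (1.22) and the matrix proteoglycan decorin, DCN (1.30, adjusted p = 0.00108), were higher. The count of 94 genes was 37 and 33 without replicates 1 and 2 of scrambled siRNA 48 h, and 38 and 40 without replicates 1 and 2 of PAX3-FOXO1 siRNA 48 h. In the same order 4, 11, 7 and 3 genes were lower, against 34, and 33, 22, 31 and 37 higher, against 60. It was 157 after quantile normalization, and 0 with the 4 arrays alone (limma, 1014 at an unadjusted p under 0.05).

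**Figure D1:**
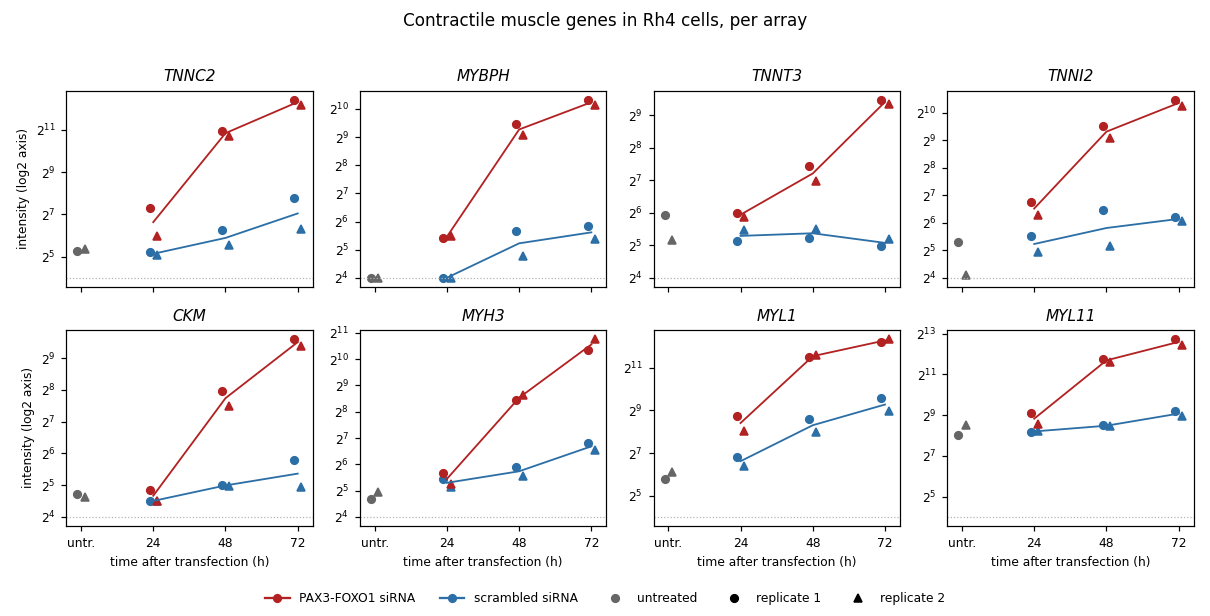
Intensity (log2 axis) of 8 contractile muscle genes on each array against the time after transfection in hours, with untreated cells at the left, circles for replicate 1, triangles for replicate 2, lines through the group means and a dotted line at the floor of 16. TNNC2 reached a mean of 5070 at 72 h after PAX3-FOXO1 siRNA and 132 after scrambled siRNA.

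At 72 h contractile genes again had the largest rises. TNNC2 was 38.4-fold higher (5.26 ± 0.49 SE, adjusted p = 0.000483), MYBPH 24.6-fold (adjusted p = 4.2e-05), the fast troponin T TNNT3 20.3-fold (adjusted p = 4.2e-05) and TNNI2 18.6-fold (adjusted p = 0.00165). The muscle creatine kinase CKM rose from 41.2 to 728 (adjusted p = 4.98e-05), and the embryonic myosin heavy chain MYH3 from 103 to 1500 (adjusted p = 4.2e-05). TNNC1, the slow and cardiac troponin C, was at the floor in all controls and at least 17.7-fold higher after the siRNA (adjusted p = 4.2e-05). LRTM1 was 14.5-fold higher. RELN was lowest relative to its control (-2.18 ± 0.32 SE, adjusted p = 0.0116), followed by CNR1 (-1.55), FGFR2 (-1.42), the exchange factor VAV3 (-1.39), COX10, an enzyme on the way to haem A (-1.39), ALDH1A3 (-1.38), the neuronal phosphoprotein DPYSL3 (-1.30) and the synaptic vesicle protein SV2A (-1.27), with adjusted p between 0.00287 and 0.0414.

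In the contractile list 19 of 48 genes rose at 72 h, 0 fell and 29 did not pass (26 and 0 adjusted over the list alone). The median was 0.72 (camera adjusted p = 1.46e-42), a call that held with an estimated correlation (adjusted p = 0.000159). Lists of the cell cycle lay lower than other genes by camera at its preset correlation, a call lost with an estimated correlation. By fry, G2/M and mitosis (fry adjusted p = 0.0189) and G1/S and replication (fry adjusted p = 0.044) were lower at 72 h. At 48 h neither passed by fry (fry adjusted p = 0.315 and 0.226). In the list of G2/M and mitosis 3 of 42 genes fell and 0 rose (27 and 0 adjusted over the list alone), among them the mitotic kinesin KIF20A (-1.18, adjusted p = 0.0275), with a median of -0.66 (camera adjusted p = 2.13e-21, and adjusted p = 0.194 with an estimated correlation). In the list of G1/S and replication 1 of 38 genes fell (7 adjusted over the list alone), with a median of -0.48 (camera adjusted p = 2.01e-12, and adjusted p = 0.223 with an estimated correlation). CDKN1A, the p21 inhibitor of cyclin-dependent kinases, rose 2.05-fold, from 892 to 1830 (adjusted p = 0.0303). The reported fusion targets had 3 lower and 1 higher, TNNC2 (12 and 3 adjusted over the list alone), with a median of -0.38 (camera adjusted p = 0.000111, and adjusted p = 0.223 with an estimated correlation). This list is not independent evidence here either. DCN rose by 1.42 on the log2 scale (adjusted p = 0.000475), the 1 of 13 fibroblast markers that passed (2 adjusted over the list alone). That list's median was 0.20 (camera adjusted p = 0.0328, and adjusted p = 0.194 with an estimated correlation). The integrin ITGA2 was at least 1.63-fold higher (adjusted p = 0.0373). In all 67 genes were higher and 32 lower, a total of 99. This total was 54 without scrambled siRNA 72 h replicate 1 (39 higher, 15 lower), 76 without scrambled siRNA 72 h replicate 2 (40 higher, 36 lower), and 59 and 50 without replicates 1 and 2 of PAX3-FOXO1 siRNA 72 h (48 higher and 11 lower, 44 higher and 6 lower). Replicate 2 of PAX3-FOXO1 siRNA at 72 h shared the lowest median correlation with the other arrays, 0.965. The total of 99 was 173 after quantile normalization (57.8% higher against 67.7%), and 0 with the 4 arrays alone (limma, 1017 at an unadjusted p under 0.05). With the replicate number as a block it was 258, with 118 higher and 140 lower, so that the balance turned.

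Taking the mean of the 3 times, each against its own control, set 6 arrays against 6. Over the times 169 genes were higher and 354 lower. Among genes whose groups did not overlap at any time, the largest rises were those of TNNC2 (15.0-fold, 3.90 ± 0.28 SE), MYBPH (at least 10.4-fold, its control at 24 h being at the floor), TNNI2 (8.02-fold), PALMD (7.39-fold), MYL1 (6.41-fold), MYL11 (5.48-fold), LRTM1 (5.41-fold) and TNNT3 (4.85-fold), with adjusted p between 8.66e-06 and 0.000197. The largest falls against scrambled siRNA were those of INSM1 (-1.90), FGFR2 (-1.83), KHDRBS3 (-1.81), RELN (-1.72), ALDH1A3 (-1.59), NELL1 (-1.50) and WEE1, the kinase that holds CDK1 inactive (-1.48). CNR1, at the floor after PAX3-FOXO1 siRNA at 24 h, was at least 2.79-fold lower. Adjusted p for these genes lay between 3.97e-05 and 0.00628. In the contractile list 24 of 48 genes rose and 0 fell (29 and 0 adjusted over the list alone), with a median of 0.40 (camera adjusted p = 6.38e-33, and adjusted p = 0.000379 with an estimated correlation). Of the myogenic regulators MEF2C rose 2.19-fold (adjusted p = 0.00226), the Notch-responsive repressor HEY1 rose 2.02-fold (adjusted p = 0.00466), and the transcriptional co-activator EYA2 fell by 0.68 (adjusted p = 0.0193), while 17 of 20 did not pass (2 higher and 1 lower adjusted over the list alone). That list's median was 0.20 (camera adjusted p = 0.0344, and adjusted p = 0.605 with an estimated correlation).

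Of the reported fusion targets 16 fell over the times and 3 rose (20 and 3 adjusted over the list alone). PIPOX (-1.30), NELL1 and CNR1 were among those lower, and TNNC2, RASSF4 (1.07) and the microtubule protein DCX (0.68) were those higher. The median was -0.50 (camera adjusted p = 5.32e-11, and adjusted p = 0.0547 with an estimated correlation), and the list is not independent evidence. Genes of G2/M and mitosis were lower in 12 of 42 cases and higher in 0 (23 and 0 adjusted over the list alone). Examples were ECT2, an exchange factor of cytokinesis (2.29-fold lower, adjusted p = 0.00737), the checkpoint kinase BUB1 (-0.84, adjusted p = 0.0383) and the spindle kinesin KIF11 (-0.75, adjusted p = 0.0102). Their median was -0.38 (camera adjusted p = 1.13e-12, adjusted p = 0.311 with an estimated correlation, and fry adjusted p = 0.0118). Among genes of G1/S and replication 8 of 38 fell (13 adjusted over the list alone), with CDC25A, a phosphatase that activates cyclin-dependent kinases (-1.11, adjusted p = 0.00371), and the replication factor MCM10 (-0.76, adjusted p = 0.00773). The median of this list was -0.32 (camera adjusted p = 1.93e-10, adjusted p = 0.311 with an estimated correlation, and fry adjusted p = 0.0132). Of the fibroblast markers DCN (0.90) and the smooth muscle and fibroblast protein TAGLN (0.78) rose and COL3A1 fell by 0.27, with the same counts over the list alone and a median of 0.10 (camera adjusted p = 0.0344, and adjusted p = 0.203 with an estimated correlation).

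**Figure D2:**
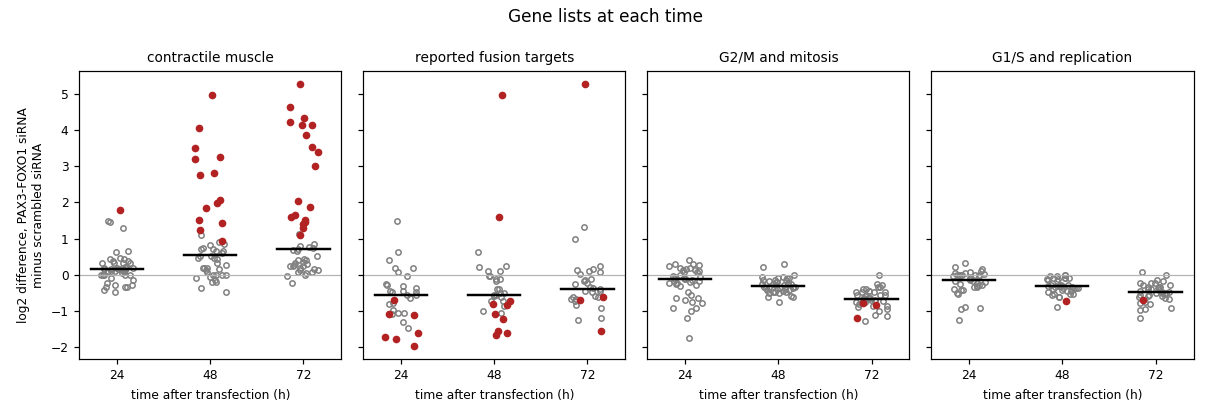
Log2 difference between PAX3-FOXO1 siRNA and scrambled siRNA for each measured gene of 4 lists at 24, 48 and 72 h, with filled points for genes at an adjusted p under 0.05 and bars at the list medians. The median of the 48 contractile genes was 0.16, 0.56 and 0.72 at these times, and that of the 42 genes of G2/M and mitosis was -0.13, -0.30 and -0.66.

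The remaining lists gave no call by camera over the 3 times, though single members passed. By fry, 2 of them were lower, FGF receptor and MAP kinase feedback (fry adjusted p = 0.0215) and neuronal genes (fry adjusted p = 0.0118). In the list of FGF receptor and MAP kinase feedback genes FGFR2, the ETS factor ETV5 (-1.06) and the ERK phosphatase DUSP6 (-0.92) fell while DUSP4 (1.02) rose, in all 4 lower and 1 higher of 22 (camera adjusted p = 0.324). In the extracellular matrix list 6 of 42 genes fell, among them the oxidase LOXL2 (-0.83) and the basement membrane collagen COL4A1 (-0.59), and DCN and COL5A1 (0.48) rose (camera adjusted p = 0.981). Neuronal genes had 5 of 29 lower, among them CNR1, GRIA2 (-1.45) and DPYSL3 (-0.99), and 2 higher, DCX and the synaptotagmin SYT1 (0.43) (camera adjusted p = 0.73). Among p53 targets CDKN1A rose (0.81) and GADD45A (-0.96) and the death receptor TNFRSF10B (-0.55) fell, of 19 measured (camera adjusted p = 0.74). CDKN1A was also the 1 gene to pass of 13 cyclins and cyclin kinase inhibitors (camera adjusted p = 0.903). Targets of FOXO factors had ERBB3 (0.74) and the mitochondrial kinase PINK1 (0.60) higher and GADD45A lower, of 18 (camera adjusted p = 0.314). In the apoptosis list the initiator caspase CASP9 (0.48) rose and TNFRSF10B fell, of 24 (camera adjusted p = 0.73). In the cell adhesion list the tetraspanin CD9 (-0.81) and CDH3 (at least 1.42-fold lower, at the floor after PAX3-FOXO1 siRNA) fell, of 30 (camera adjusted p = 0.73). The interferon-induced GTPase GBP1 (at least 1.73-fold lower, at the floor after PAX3-FOXO1 siRNA at 24 h) was the 1 of 36 interferon response genes to pass (camera adjusted p = 0.95). The phosphatase subunit PPP1R15A (0.31) was the 1 of 29 genes of endoplasmic reticulum stress and amino acid response (camera adjusted p = 0.903), and the glycolytic regulator PFKFB3 (-0.62) the 1 of 29 genes of hypoxia and glycolysis (camera adjusted p = 0.91). No gene passed by limma among 14 of IGF and insulin signalling, 20 of cholesterol synthesis, 39 ribosomal proteins or 37 of oxidative phosphorylation (camera adjusted p = 0.91, 0.759, 0.497 and 0.981). The same held for the markers of other cell types, 12 epithelial, 15 blood and 9 endothelial (camera adjusted p = 0.73, 0.981 and 0.73). Adjusted over the list alone, these 7 lists had 0 genes higher and 0 lower. The other counts adjusted over the list alone, higher and lower, were 1 and 6 for FGF receptor and MAP kinase feedback, 3 and 8 for extracellular matrix, 2 and 6 for neuronal genes, 1 and 2 for cyclins, 3 and 1 for FOXO targets, 1 and 3 for cell adhesion and 1 and 3 for hypoxia and glycolysis, and unchanged for the rest.

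The total of 523 genes over the 3 times was 273 without scrambled siRNA 48 h replicate 1 (120 higher, 153 lower), 289 and 299 without replicates 1 and 2 of scrambled siRNA 24 h, 319 without scrambled siRNA 72 h replicate 1, 317 without PAX3-FOXO1 siRNA 48 h replicate 2 and 316 without PAX3-FOXO1 siRNA 72 h replicate 2. At least a 2-fold change was reached by 46 of the genes higher and 50 of the genes lower.

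**Figure D3:**
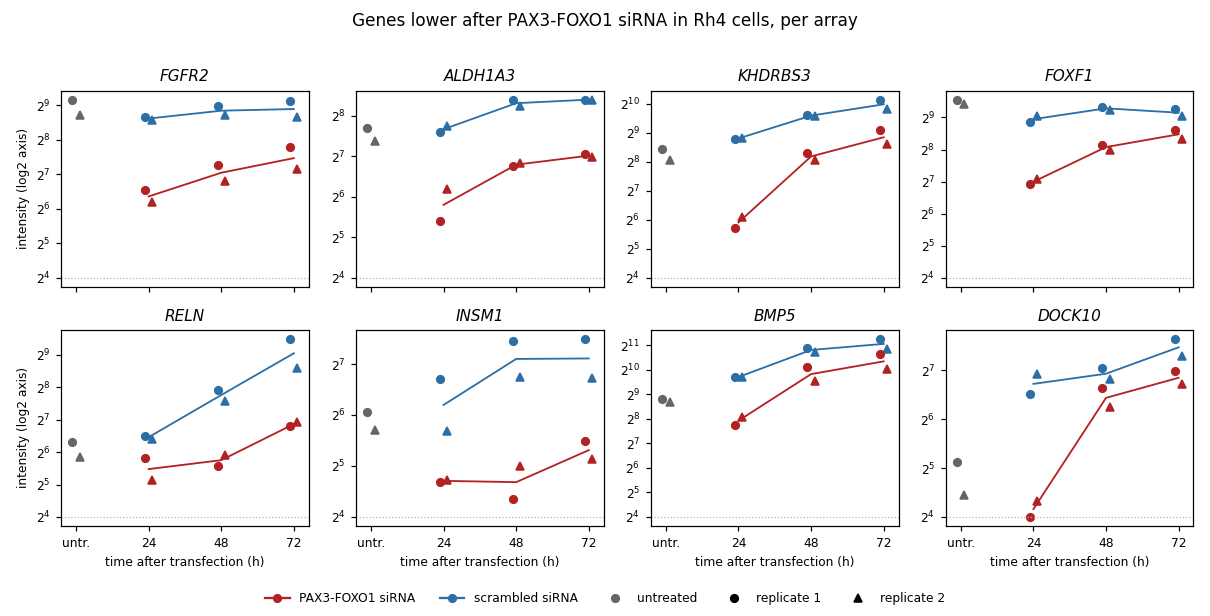
Intensity (log2 axis) of 8 genes lower after PAX3-FOXO1 siRNA on each array against the time after transfection in hours, with untreated cells at the left, circles for replicate 1, triangles for replicate 2, lines through the group means and a dotted line at the floor of 16. BMP5 had means of 837, 1800 and 2140 after scrambled siRNA and 244, 909 and 1300 after PAX3-FOXO1 siRNA.

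How the calls at the 3 times overlapped was counted among the 10836 genes, each time with its own controls. The genes higher at 48 h and at 72 h shared 41, against 0.37 for independent lists, and those lower shared 17, against 0.10 (one-sided Fisher's exact tests across genes, p = 7.09e-83 and 1.19e-36). Between 24 h and 48 h 4 higher and 17 lower genes were shared (one-sided Fisher's exact tests, p = 1.26e-08 and 2.45e-36), and between 24 h and 72 h 2 higher and 9 lower (p = 0.000556 and 1.83e-16). Genes are not independent replicates, and the calls at the 3 times rest on 1 shared spread per gene. A gene with a small spread can thus pass at several times even where its effects are unrelated. Independent lists are therefore no fair reference, and these p-values describe the overlap only. MYL1 and PALMD were higher at all 3 times. FGFR2, ALDH1A3 and KHDRBS3 were among the 9 genes lower at all 3. The other 6, named here after their values were seen, were the urea cycle enzyme ASS1, the death-associated kinase DAPK1, NKAIN1, the desmosomal protein PKP1, the salivary protein STATH and the ubiquitin-editing enzyme TNFAIP3. Over the times ASS1, with the smallest log2 difference of these, fell by 0.80, and STATH, with the largest, fell by 1.28.

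The difference of the effect between 72 h and 24 h was tested directly. For 19 genes the log2 difference at 72 h lay above that at 24 h, and for 0 it lay below. By limma 588 of 10836 genes had an unadjusted p under 0.05 in both directions together. That is near the share of 0.05 expected with no effect. Among them were CKM (3.98 ± 0.39 SE, adjusted p = 0.00275), MYH3 (3.72 ± 0.34 SE, adjusted p = 0.00231), TNNT3 (3.69 ± 0.39 SE, adjusted p = 0.00383) and LRTM1 (3.45 ± 0.46 SE, adjusted p = 0.0182). TNNC1 passed too (adjusted p = 0.00231), but it was at the floor in both groups at 24 h, so its value of 4.14 is neither a lower nor an upper bound. DCN (1.46, adjusted p = 0.0145) and ITGA2 (at least 2.35-fold, its control at 72 h being at the floor, adjusted p = 0.0347) also passed, and TNNC2 did not (3.77, adjusted p = 0.113). Of the 48 contractile genes 10 passed, all with the larger value at 72 h (22 adjusted over the list alone), and the list median was 0.68 (camera adjusted p = 3.86e-29, and adjusted p = 0.000571 with an estimated correlation). No gene of the other called lists passed by limma. Reported fusion targets had a median of 0.31 (camera adjusted p = 3.19e-05, 3 higher adjusted over the list alone, adjusted p = 0.34 with an estimated correlation). Genes of G1/S and replication had -0.24 (camera adjusted p = 7.36e-05, and adjusted p = 0.66 with an estimated correlation), and genes of G2/M and mitosis -0.47 (camera adjusted p = 4.84e-11, and adjusted p = 0.412 with an estimated correlation). The count of 19 was 9 without scrambled siRNA 24 h replicate 1, 11 without scrambled siRNA 24 h replicate 2, 9 without PAX3-FOXO1 siRNA 72 h replicate 1 and 81 without PAX3-FOXO1 siRNA 24 h replicate 2. The one-sided direction did not hold throughout. Of these 81 genes 56 lay above and 25 below, without PAX3-FOXO1 siRNA 24 h replicate 1 there were 13 above and 6 below, and without scrambled siRNA 72 h replicate 2 there were 11 above and 5 below. It was 3 with the 8 arrays of these times alone, and 24 after quantile normalization, of which 21 lay above and 3 below.

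Scrambled siRNA against untreated cells showed what the control transfection and its time in culture changed together. The labels give no time for the untreated cells, so neither can be told from the other. Over the 3 times 117 genes were higher and 17 lower. The values stand against a median over all genes of 0.102 on the log2 scale, a shift of the arrays as deposited. CPT1A, which carries long-chain fatty acids into mitochondria, was 5.35-fold higher (2.42 ± 0.27 SE, adjusted p = 0.00419), and the fatty acid transporter CD36 was 4.96-fold higher (adjusted p = 0.00419). DOCK10 (2.26), MYL1 (2.11), LRRC17 (2.00), the protease PRSS23 (1.93), the small muscle protein SMPX (1.90) and BMP5 (1.78) followed, with adjusted p between 0.00419 and 0.0137. The immediate early transcription factors EGR1 and FOS had the lowest values (-2.27 and -1.85, adjusted p = 0.0171 for each). The keratin KRT23 (-1.14) and MPPED2 (-1.14) were lower as well, and LGI2, the myosin light chain kinase MYLK, the small GTPase RRAD and the Rac exchange factor PREX2, each at the floor after scrambled siRNA at some or all times, were at least 2.70-fold, 2.20-fold, 2.03-fold and 1.80-fold lower, with adjusted p between 0.00153 and 0.0488.

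Muscle genes were among those higher after scrambled siRNA. In the contractile list 4 of 48 rose and 0 fell (12 and 0 adjusted over the list alone), with MYL1, the slow troponin I TNNI1 (1.30, adjusted p = 0.0313) and MYH3 (1.09, adjusted p = 0.0313) as examples. The list median was 0.18 against 0.102 over all genes (camera adjusted p = 0.0282, and adjusted p = 0.776 with an estimated correlation). MEF2C was 2.71-fold higher (adjusted p = 0.0167), the 1 of 20 myogenic regulators to pass. Genes of endoplasmic reticulum stress and amino acid response had 2 of 29 higher (7 adjusted over the list alone), one of them the chaperone cofactor DNAJB9 (0.98, adjusted p = 0.0467), and a median of 0.30 (camera adjusted p = 0.0457, and adjusted p = 0.776 with an estimated correlation). Below other genes lay the lists of G1/S and replication (median -0.06, camera adjusted p = 0.012) and of ribosomal proteins (median -0.04, camera adjusted p = 0.00298), with 0 genes passing by limma in either list and adjusted p = 0.776 with an estimated correlation in both. The sterol enzyme MSMO1 (1.47), LOXL2 (1.07), the integrin ITGA4 (1.13) and COL3A1 (0.69) were single members of other lists that rose. The count of 134 was 11 without untreated replicate 2, with 2 higher and 9 lower, so that the direction of the balance turned. It was 144 without untreated replicate 1 with 67 genes shared, 35 without scrambled siRNA 24 h replicate 1, 35 without scrambled siRNA 24 h replicate 2, 27 without scrambled siRNA 48 h replicate 1 and 36 without scrambled siRNA 72 h replicate 1. It was 313 in the upper 60% of genes by mean and 1 with the 8 arrays alone. Centring each array on its median gave 63 (73% higher against 87.3%), quantile normalization gave 162 (69.1% higher), and leaving out PAX3-FOXO1 siRNA 24 h replicate 1, which enters only through the shared spread, gave 221.

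Scrambled siRNA at 72 h against 24 h showed what further time after transfection changed without the knockdown. No untreated arrays are labelled with these times, so time in culture and a changing response to transfection cannot be told apart. Here 18 genes were higher and 5 lower. The cancer-testis antigen gene SAGE1 was 6.61-fold higher (2.72 ± 0.39 SE, adjusted p = 0.034), MYL1 6.32-fold (adjusted p = 0.0178), RELN 6.00-fold (adjusted p = 0.0221), SMPX 5.25-fold (adjusted p = 0.0335) and MEF2C 4.13-fold (adjusted p = 0.0221). LRRC17 (2.24), CD36 (1.95), the phosphatase PTPRR (1.85) and the matrix protein FN1 (0.99) rose too. The cold-inducible RNA-binding protein RBM3 (-1.88), the mitochondrial carrier UCP2 (-1.30), the Dickkopf receptor KREMEN2 (-1.18), the cullin CUL9 (-1.13) and the synaptic adhesion gene NRXN3 (-0.60) were lower, with adjusted p between 0.0221 and 0.0424. In the contractile list 2 of 48 genes rose and 0 fell (12 higher and 1 lower adjusted over the list alone), with a median of 0.13 (camera adjusted p = 6.73e-06, and adjusted p = 0.0767 with an estimated correlation). The reported fusion targets had a median of 0.23 with 0 passing by limma (camera adjusted p = 0.000794, 5 higher and 2 lower adjusted over the list alone, adjusted p = 0.321 with an estimated correlation), not independent evidence. Genes of G1/S and replication had -0.24 with 0 passing by limma (camera adjusted p = 0.000537, and adjusted p = 0.622 with an estimated correlation). The count of 23 was 0 without scrambled siRNA 24 h replicate 1 (limma, 549 at an unadjusted p under 0.05), 1 without scrambled siRNA 24 h replicate 2, 2 without scrambled siRNA 72 h replicate 1 and 36 without scrambled siRNA 72 h replicate 2. It was 54 after quantile normalization, 37 with arrays centred on their medians, 35 in the upper 60% of genes, and 0 with the 4 arrays alone (limma, 1074 at an unadjusted p under 0.05).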

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

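The count over other splits of the arrays was planned before its result was known. The tests on scaling, on single replicate numbers and on the scrambled and untreated arrays were chosen after the results they concern had been seen.

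The effect of PAX3-FOXO1 siRNA differed between 72 h and 24 h, by limma's test of the difference, for 12 genes of the naming rule. The log2 values were 3.98 for CKM, 3.72 for MYH3, 3.69 for TNNT3, 3.45 for LRTM1, 3.16 for MYBPH (an upper bound, with its control at 24 h at the floor), 3.05 for the perinatal myosin heavy chain MYH8, 2.89 for MYL11, 1.93 for the calcium-binding calsequestrin CASQ2, 1.65 for UCP2, 1.46 for DCN and 1.24 for ITGA2 (a lower bound, with its control at 72 h at the floor). TNNC1 had 4.14, which bounds nothing, since both of its groups at 24 h were at the floor. Contractile muscle genes (median 0.68), reported fusion targets (0.31), genes of G1/S and replication (-0.24) and genes of G2/M and mitosis (-0.47) differed as lists, and the contractile list was the 1 of these 4 to keep its call with an estimated correlation. Outside the genes tested, 80 of 2551 probe sets that match several genes or none passed over the 3 times, 28 higher and 52 lower.

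Over the 6 against 6 siRNA arrays, with time as a covariate, the real split gave 575 genes and the highest of the other splits drawn gave 28. Of 100 splits, out of 462 possible, 1 gave as many genes as the real one, and that was the real split itself. This argues against a chance division of the arrays but does not exclude it. Every other split set arrays of both siRNAs on each side, so any siRNA effect adds to its spread, and 90 of them gave 0 genes. The labels also do not say that the arrays are separate cultures. The split that gave 28 set 5 scrambled arrays and 1 PAX3-FOXO1 siRNA array against the rest and parted 4 of the 6 pairs of the same time and replicate number. The 4 other splits drawn that part all 6 pairs, as the real one does, gave 0 genes by limma, with 269 to 897 genes at an unadjusted p under 0.05 against 1965 in the real split.

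Contractile muscle genes were higher after PAX3-FOXO1 siRNA at 72 h, with a list median of 0.72. After quantile normalization the median was 0.74, with 0.65 and 0.90 within replicate numbers 1 and 2, which argues against scaling between arrays as the source. The lower of the medians within a replicate number was 0.64, which argues against 1 replicate number alone. It stays open whether the siRNA may have sped up genes already rising with time after scrambled transfection. The 60 genes higher at 48 h had a median of 0.06 in scrambled siRNA at 72 h against 24 h (0.14 and 0.01 within the numbers), with 33 of 60 above 0. The contractile list itself had a median of 0.13 there (camera adjusted p = 6.73e-06, and adjusted p = 0.0767 with an estimated correlation), with 27 of 48 above 0. That comparison shares the scrambled arrays of 72 h with the 72 h effect. Loss of the fusion, the biological explanation that the groups name, was not tested apart from other effects of the siRNA.

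The 34 genes lower at 48 h, far fewer with 1 array of that time left out, had a median of 0.40 in scrambled siRNA at 72 h against 24 h (0.48 and 0.31 within replicate numbers 1 and 2, with 24 of 34 above 0). This argues against genes that were falling with time after scrambled transfection and were sped up. In PAX3-FOXO1 siRNA at 24 and 72 h against untreated cells their median was -0.71 (-0.74 and -0.73, not set against all genes), which argues against a rise in the scrambled control alone. These arrays entered the choice of the genes only through the shared spread. Whether the control had moved from untreated cells stays open. In scrambled siRNA at 24 and 72 h against untreated cells the median was 0.19 relative to all genes (0.20 and 0.19, with 27 of 34 above 0 and quartiles of 0.05 and 0.71), next to the bound of 0.2 set for this test, and leaving it open so near the bound was decided after the value was seen. Loss of the fusion was again not tested apart from other effects of the siRNA.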

How the results depend on the processing

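The floors of 32 and none, and leaving out PAX3-FOXO1 siRNA 24 h replicate 1 from every fit, were chosen after seeing the data. All 7 counts stayed within 1.5 times under every probe set on its own, the mean of a gene's probe sets, no intensity trend and the other floors. Elsewhere the cause of a move was not tested, save that fits to the compared arrays alone have fewer arrays, leave-one-out fits rest on an array assumed to vary like the other groups, and the upper 60% tests fewer genes. In the order 24 h, 48 h, 72 h, mean of the times, difference between times, scrambled against untreated and scrambled over time, the counts were 39, 94, 99, 523, 19, 134 and 23. With the replicate number as a block they were 148, 186, 258, 969, 32, 818 and 85, and each set held all genes of the fit without it. At 48 h the block gave 97 genes higher and 89 lower, against 60 and 34, and at 72 h 118 higher and 140 lower, against 67 and 32. Same-numbered arrays may share a batch, since 19 of 21 correlations of their deviations exceeded 0.1, all of those between groups compared directly among them. Of 14 arrays 9 were closest to an array with their own number. This is weak evidence alone, since nearly as many other arrays had the same number as had the other one. The rule asked for every correlation, the labels name no batch, and so the block was not made the basis of any result. With the arrays compared alone they were 0, 0 and 0 at 24, 48 and 72 h (limma, 962, 1014 and 1017 at an unadjusted p under 0.05), 3 for the difference, 1 for scrambled against untreated and 0 for scrambled over time (1074 at an unadjusted p under 0.05), while the mean of the times gave 536. Quantile normalization gave 67 at 24 h, 157 at 48 h, 173 at 72 h and 54 for scrambled over time. Median centring gave 63 for scrambled against untreated and 37 for scrambled over time. The upper 60% gave 97 at 24 h, 313 for scrambled against untreated and 35 for scrambled over time. At least a 2-fold change was reached by 96 genes in the mean of the times and 65 in scrambled against untreated. Scrambled against untreated gave 221 without PAX3-FOXO1 siRNA 24 h replicate 1, which gave 101 at 48 h, 94 at 72 h and 18 for scrambled over time. Leaving out each replicate in turn gave 2 to 285 genes at 24 h, 33 to 40 at 48 h, 50 to 76 at 72 h, 273 to 661 for the mean, 9 to 81 for the difference, 11 to 144 for scrambled against untreated and 0 to 36 for scrambled over time (at 0, limma, 549 at an unadjusted p under 0.05). The dimmer FOXO1 probe set had -0.43 over the times in both fits and passed with the block only (adjusted p = 0.0143, against 0.197 to 0.566 in the other alternatives, and at 72 h alone 0.0248 with the block), and leaving out replicates gave -0.53 to -0.33, and -0.31 to -0.03 for the brighter one. Of the 30 list calls, 4 held with an estimated correlation, all of the contractile list (48 h, 72 h, mean and difference), 16 with fry, 28 with the mean of probe sets, 26 in the upper 60% and 29 with the block, which changed no other list call than that of G1/S and replication at 24 h (adjusted p = 0.0575). Of 2591 alternative values of the 155 results for single named genes 2000 kept their call, 591 kept their direction but lost the threshold, and 0 reversed. That 0 reversed was largely fixed in advance. The block, no intensity trend and the compared arrays alone leave a log2 difference unchanged. All genes called at a single time had groups that did not overlap, so leaving out an array could not turn their direction. Changes below an intensity of 16 cannot be seen.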

Other observations

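The list of fatty acid genes below was written before its members' values were seen. The comparison of the time course with the 48 h effect and the genes of the next paragraph were chosen after values had been seen.

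Several of the genes lower after PAX3-FOXO1 siRNA had risen in the scrambled controls over untreated cells. DOCK10 had an intensity of 27.6 in untreated cells, 106, 122 and 178 after scrambled siRNA at 24, 48 and 72 h, and 17.9, 86.8 and 115 after PAX3-FOXO1 siRNA. RELN had 67.5 in untreated cells, 87.9, 216 and 527 after scrambled siRNA, and 44.5, 53.8 and 116 after PAX3-FOXO1 siRNA. KHDRBS3 had 309 in untreated cells, 449, 775 and 1020 after scrambled siRNA, and 60.2, 292 and 462 after PAX3-FOXO1 siRNA. BMP5 had 431 in untreated cells, 837, 1800 and 2140 after scrambled siRNA, and 244, 909 and 1300 after PAX3-FOXO1 siRNA. At 72 h after PAX3-FOXO1 siRNA these genes lay above untreated cells. There they had risen less than in the control, not fallen. FGFR2, also lower after PAX3-FOXO1 siRNA, had not risen in the controls, with 493 in untreated cells, 392, 459 and 475 after scrambled siRNA, and 82.0, 132 and 177 after PAX3-FOXO1 siRNA. UCP2 went the other way, with 1070 in untreated cells, 1060, 504 and 430 after scrambled siRNA, and 1230, 1380 and 1570 after PAX3-FOXO1 siRNA. Among master regulators of muscle, MYOD1 and MYOG had log2 differences of -0.07 and -0.02 over the 3 times (adjusted p = 0.813 and 0.975), with MYOG at or near the floor. Across 10836 genes, which are not independent replicates, the effect of the siRNA at 48 h and the change of scrambled siRNA from 24 h to 72 h, which share no array, correlated at -0.02 (Pearson) and -0.03 (Spearman).

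CPT1A and CD36 rose after scrambled transfection, and a candidate explanation is lipid brought in by the transfection reagent or spent medium that acts on a shared set of fatty acid genes. It was tested on 29 other genes of fatty acid uptake and oxidation, of which 24 were measured. Of these 19 had values above 0, with a median of 0.15 against 0.10 over all genes, none passed by limma, and camera gave p = 0.293 (0.582 with an estimated correlation). The largest were the electron transfer flavoprotein subunit ETFA (0.97, adjusted p = 0.106) and the carnitine acetyltransferase CRAT (0.77, adjusted p = 0.258). The test leaves the explanation open. The bound set in advance, a p above 0.2, was badly chosen, since a p that misses its threshold excludes nothing.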
